A study of Gallus gallus with 9 samples.

How the data were processed

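Expression was measured in 9 pools of embryonic chicken liver (total RNA), 4 male and 5 female, each made of 4 livers according to the labels, with 1 array per pool. The age of the embryos is not given in the sources used here. Pools are separate birds, so the spread between pools covers biological and technical variation together, and each p measures the spread between these pools only. The pool letters were not taken as pairing male and female pools.

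The deposited values are intensity on a linear scale, 1 per probe set and array, for 38535 probe sets. No label names the software that made them. The mean over probe sets without the top and bottom 2% was equal on all arrays, about 2501, so the arrays had been scaled to a common trimmed mean before deposit. Control probe sets (96) were left out of the tests, which leaves 38439.

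Values were quantile normalized between arrays and transformed to log2(intensity + 49.8), the pseudocount being the 10th percentile of all values. Quantile normalization followed from a rule that keeps values as deposited only if the array medians lie within 0.1 log2 of each other, and they ranged over 0.21. Genes and chromosomes came from the probe set annotation and the reference gene table (assembly GRCg7b). Of the tested probe sets, 27168 had 1 gene, 177 had several and 11094 had none; 26853 were placed by gene identifier, 314 by symbol, and 1 was not placed. Each of 13007 genes was represented by its brightest probe set, with 609 genes on Z and 17 on W. No coordinates are printed, because the table of values names no genome build; the reference served for chromosome, gene order and distance to DMRT1. A further 746 probe sets have names outside the main chicken series and were tested with the rest.

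Single probe sets and genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p below 0.05). Expressed genes are those with a mean log2 above 9.20, the median of all probe sets. The Z index of a pool is the median over expressed Z genes of the deviation from the gene's mean over 9 arrays, minus the same median over autosomal genes. Male and female indices were compared by a two-sided exact permutation test over all 126 splits of the pools into 4 and 5, whose smallest p is 0.00794. The same test served for genes within 5 Mb of DMRT1 against other Z genes, for Z genes with a W copy against other Z genes, for the brightest against the dimmest of 3 equal groups of all Z genes, for 10 blocks along Z and for each chromosome. The test permutes pools with the genes fixed, so it does not ask whether another set of Z genes would differ as much. Gene order was shuffled 10000 times to judge the lowest running median of 15 genes.

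The 24 gene lists were those of secreted hepatocyte proteins; egg-yolk genes; sterol and bile acid synthesis; fatty acid synthesis; fatty acid oxidation; glycolysis; drug metabolism; the growth hormone axis; steroid hormone conversion; one-carbon and amino acid metabolism; erythroid cells; macrophages and granulocytes; endothelium and stroma; bile duct; pancreas; gonad and adrenal; muscle and kidney; proliferation; interferon response; chaperones; immediate early genes; circadian clock; respiratory chain; and ribosomal proteins. Autosomal members were tested with camera at a preset correlation of 0.01 against other autosomal genes, with the estimated correlation, fry and a permutation of pools beside it. List members were matched by symbol or alias, and some matched by alias stand for a relative of the listed gene.

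Named genes followed a rule: up to 8 W genes by size of difference, the 12 Z genes furthest toward males and up to 6 toward females, 8 autosomal genes in each direction among those called above the level filter, called Z members and up to 3 autosomal members per list by smallest p, and DMRT1, HINTW and CHD1. Some other list members were named after their values were seen, to show the range: SQLE, MVD, CYP51A1, HMGCS1, LYZ, FOXL2, AMH and PCNA. W genes with only a LOC number were counted, not listed. The groups, tests, lists, named-gene rule and first set of other settings were fixed before the data were examined.

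The other settings in that first set were pseudocounts at the 1st and 25th percentile, quantile normalization (which became the setting used), centring each array on autosomal genes, level filters at the 50th and 75th percentile, eBayes without a trend, the mean of probe sets per gene, the letter as a block, windows of 2 and 10 Mb, the mean over genes, and leaving out each pool. Chosen after seeing the data were values as deposited, plain probe sets alone, leaving out male B for its bright spiked controls (the same fit as leaving out that pool), camera with a trend, W copies matched by synonym, and the removal of PODXL, which had entered the glycolysis list through an alias of another gene. Camera with a trend and the synonym match were for a time used as the setting reported, after the values without them had been seen. They were put back to the written design and are given as alternatives. The mitochondrial ribosome comparison, the run beside DMRT1 and the further counts of autosomal genes in other splits (at the p limit of the real split, and adjusted over autosomal genes alone) were also chosen after seeing the data. An exploratory pass, a trial of settings and 1 full run came before the values given here.

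The pipeline was tested on simulated data with the spread of these arrays. A simulated log2 difference of 0.5 was called for 23 of 64 genes (35.9%), 1 for 49 of 63 (77.8%) and 2 for 57 of 59 (96.6%). Of 12172 unchanged autosomal genes 10 were called, and with nothing changed 0 were called. A simulated Z shift of 0.4 was returned as 0.40. The simulated values were added on the same log2(intensity + pseudocount) scale, the same for every Z gene and without background. The return of 0.40 therefore checks the computation, and cannot show that a true ratio of transcript is recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.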

Results

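RNA from whole livers of embryonic chickens was measured on 9 expression arrays, each holding a pool of 4 livers from birds of 1 sex. There were 4 male pools (A, B, D and E) and 5 female pools (A to E). Male birds carry 2 Z chromosomes and females 1 Z and 1 W, so the comparison asks how far sex chromosome dose, and sex more widely, showed in liver expression. Median intensity per array ranged from 565 in female B to 661 in male D, and correlations between arrays ranged from 0.966 to 0.981. The spiked control transcripts, added to every sample, were brighter in male B (mean log2 14.69) than in the other 8 arrays (14.04 to 14.17), and the male and female means of these controls differed by 0.18 (exact permutation p = 0.0714). The number of arrays limits the precision of every value below. Differences are male minus female on the log2 scale, with the standard error (SE) of the limma fit for single genes, and n = 4 male and 5 female pools throughout.

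W-linked genes separated the sexes. HINTW, the W-linked relative of the nucleotide hydrolase gene HINT1, averaged 16.93 ± 0.13 (SD, n = 5) in females and 7.33 ± 0.57 (SD, n = 4) in males, a difference of −9.60 (SE 0.21, adjusted p = 4.9e-11). The W copies UBAP2L2 (−3.58, SE 0.47), HNRNPKL (−3.43, SE 0.51), SPIN1L (−3.42, SE 0.42) and UBE2R2L (−2.70, SE 0.30) were also higher in females. Of 17 genes that the reference places on W, 10 passed the limma test, all of them higher in females, and 5 of these 10 carry names that are only LOC numbers. UBE2R2L was named after its values were seen. The male mean of 9 of the 10 lay at or below the brightest control probe set with no transcript added (log2 8.67), so the ratio of these genes is limited by background, and 6 W genes passed when only genes above the level filter were tested. MBD2 (0.21, adjusted p = 0.286) and NEDD4L (0.33, adjusted p = 0.428), placed on W by the reference, had clear male signal, at male means of 13.87 and 11.44. Both were named after their values were seen. The index of the 10 called genes ran from −2.45 to −1.89 in male pools and from 1.41 to 1.84 in female pools, so no pool contradicted its sex label. These genes were picked by a test of the same labels, so this separation is partly built in, and the 7 W genes without a call are left out. HINTW was named as a check before the data were examined.

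In array signal, Z-linked genes as a group were higher in males, by less than the 2-to-1 dose. Across 425 expressed Z genes, the Z index of a pool (the median deviation of Z genes from their own means, relative to autosomal genes) averaged 0.22 ± 0.033 (SD, n = 4) in males and −0.17 ± 0.015 (SD, n = 5) in females. The difference was 0.39 (SE 0.018), a 1.31-fold higher signal in males. Background in the signal can lower such ratios, so this value does not place the transcript ratio below the dose. Every male pool (lowest 0.18) lay above every female pool (highest −0.16), with an exact permutation p = 0.00794, the smallest that the 126 splits of the pools allow. Among 30 autosomes with enough genes, the same index difference ran from −0.026 on chromosome 8 to 0.12 on chromosome 30, and 5 had an exact p below 0.05 before adjustment. Chromosomes 25 (0.074) and 8 (−0.026) also had the smallest possible p, 0.00794. None of the 31 chromosomes, Z included, passed after adjustment (adjusted p = 0.0820 for Z, 25 and 8). With so few chromosomes at the smallest possible p, Z could not have passed this adjustment at any size of shift. The adjusted p therefore does not weigh Z against chromosomes 25 and 8, whose differences were far smaller.

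**Figure D1:**
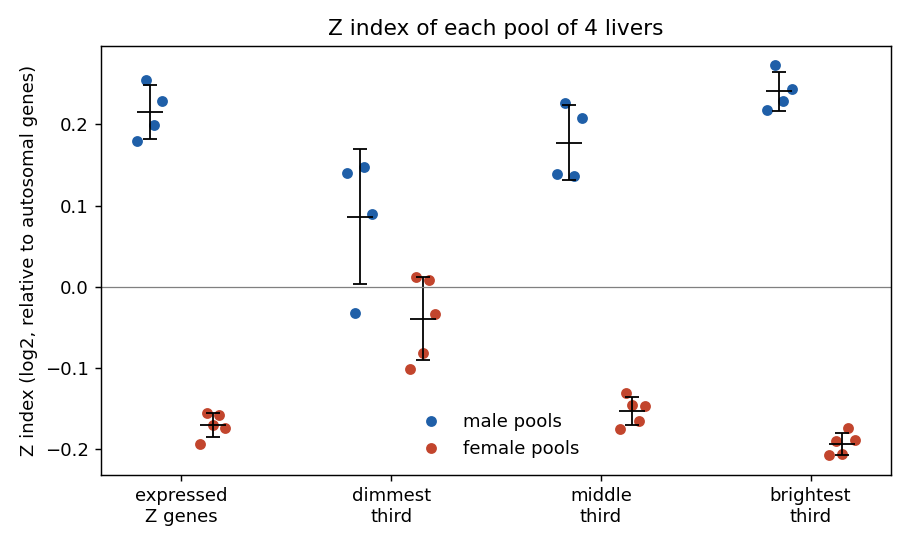
Z index of each pool (log2, relative to autosomal genes) for all expressed Z genes and for Z genes split by mean signal into 3 groups of 203; each point is 1 pool of 4 livers, the long bar is the mean and the whiskers are 1 SD. For all expressed Z genes the male pools lie at 0.18 or above and the female pools at −0.16 or below, and the sexes lie closer together among the dimmest genes.

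Signal ratios of single Z genes were spread broadly between equal expression and the dose ratio. The median difference of the 425 expressed Z genes was 0.35, with quartiles of 0.11 and 0.59 and a 5th to 95th percentile range of −0.22 to 0.84. Estimates were above 0 for 359 of them (84.5%). The 95% confidence interval lay wholly above 0 for 217 genes (51.1%), wholly below 0 for 12, and wholly below 1, the log2 of the dose ratio, for 361 (84.9%). For 166 genes it lay between 0 and 1, for 64 it held 1, and for 0 it lay above 1. The 8920 expressed autosomal genes had a median of −0.021 and an SD of 0.23, against an SD of 0.35 for Z genes. Intervals of single genes are not adjusted for the number of genes. They describe array signal, where background can lower ratios, so an interval below 1 does not place the transcript ratio below the dose.

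**Figure D2:**
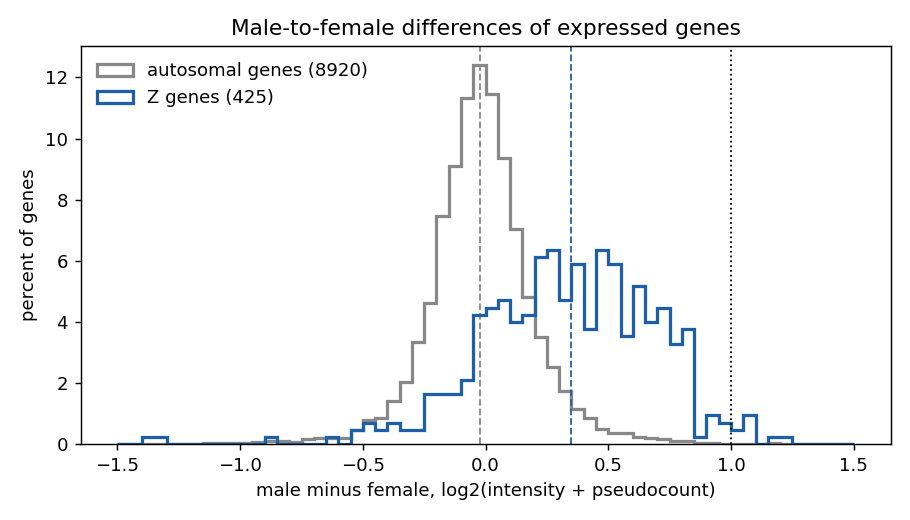
Share of genes (percent) by male-minus-female difference in log2(intensity + pseudocount), for 425 expressed Z genes and 8920 expressed autosomal genes; dashed lines mark the medians and the dotted line marks 1, the log2 dose ratio. Autosomal genes centre on −0.021, and Z genes form a broader distribution around 0.35.

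Single Z genes higher in males covered many kinds of function. RGP1, a partner of the RIC1 trafficking protein, differed by 1.16 (SE 0.13, adjusted p = 2.6e-04) and SPTLC1, a subunit of the first enzyme of sphingolipid synthesis, by 1.06 (SE 0.11). MRPL17 of the mitochondrial ribosome differed by 1.05 (SE 0.093), MED18 of the Mediator complex by 1.05 (SE 0.11) and FBP2, a fructose bisphosphatase, by 1.05 (SE 0.20). Also higher in males were LOC768709 (1.01), the dynactin subunit DCTN3 (0.995), the DNA repair gene APTX (0.97), ARSK (0.95), C5orf51 (0.95), NIPSNAP3A (0.93) and the peptide-trimming aminopeptidase gene ERAP1 (0.92). SLC1A1, a glutamate transporter, was the only called Z gene higher in females, at −1.31 (SE 0.15, adjusted p = 4.1e-04), and its 3 probe sets all passed in that direction. CHD1, a sexing marker with copies on Z and W, differed by 0.12 (adjusted p = 0.879) and DMRT1, the Z-linked testis gene, by −0.27 (adjusted p = 0.822). Of 609 Z genes, 116 passed (19.0%), 115 of them higher in males, against 35 of 12358 autosomal genes (0.283%). Among genes called higher in males, the odds ratio for Z against autosomes was 179 (Fisher's exact test, p = 2.2e-138, over genes that are not independent). FBP2 lost its call in 5 of the 9 fits that each left out a single pool (highest adjusted p = 0.0858), without a mean-variance trend and with the letter as a block, and RGP1 lost its call with the mean of probe sets per gene. The count of Z genes higher in males was 72 without a mean-variance trend and 76 with the mean of probe sets per gene, and 132 when only genes above the 50th percentile of signal were tested.

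Dim Z genes were less far apart between the sexes than bright ones. The brightest 203 Z genes were higher in males by 0.43 (SE 0.013), the middle 203 by 0.33 (SE 0.024) and the dimmest 203 by 0.13 (SE 0.047), each relative to autosomal genes of the same signal. The difference between the brightest and the dimmest group was 0.31 (SE 0.056, exact permutation p = 0.00794). Male B had the lowest male index among dim genes, −0.032, and the dimmest group alone gave an exact permutation p = 0.0317. At the top of the range the shift was smaller again: among 255 Z genes over the 75th percentile of signal, the brightest 64 differed from the rest by −0.073 (exact permutation p = 0.0159). Of the dimmest 203 genes, 123 (60.6%) had a mean at or below the brightest unspiked control.

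Z genes near DMRT1, beside the male hypermethylated region known from chicken genetics, were higher in males like the rest of Z. The 60 expressed genes within 5 Mb of DMRT1 differed from autosomal genes by 0.36 (SE 0.024) and the other 365 by 0.39 (SE 0.018). Near genes minus other Z genes gave −0.029 (SE 0.020), with an exact permutation p = 0.190. With a window of 2 Mb the difference was −0.099 (exact permutation p = 0.0159), and with probe sets of the plain kind alone it was −0.065 (exact permutation p = 0.0397). Without male B it was 0.00080 (exact permutation p = 0.982). All of these tests permute pools with the genes fixed, so they do not set the near genes against other sets of Z genes.

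Along Z, every one of 10 consecutive blocks of 42 or 43 expressed genes was higher in males than autosomal genes were, each with an exact permutation p = 0.00794. The block from UTP15 to HACD4, which holds the place of DMRT1, had the lowest shift, 0.27, and the block from COX7C to B4GALT1 the highest, 0.47. The UTP15 to HACD4 block lay 0.13 below other Z genes (difference −0.13) and the next block, RFKL to CDC14B, 0.11 below (difference −0.11), both with an exact permutation adjusted p = 0.0397. That test permutes pools with the genes fixed, so it does not ask whether other sets of Z genes would lie as low. Gene order was not shuffled for the blocks. The lowest run of 15 neighbouring genes went from VLDLR, a lipoprotein receptor, to GLDC, a glycine cleavage enzyme, with a median difference of 0.033. Within it RCL1 (0.37, adjusted p = 0.0135) was higher in males and SLC1A1 (−1.31) higher in females, and 7 of the 15 estimates were below 0, among them VLDLR at −0.41 (adjusted p = 0.359). The run differed from autosomal genes by 0.058 (exact permutation p = 0.262) and from other Z genes by −0.34 (exact permutation p = 0.00794). It was picked as the lowest of all runs after the values were seen, and 0.265 of shuffled gene orders held a run as low.

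**Figure D3:**
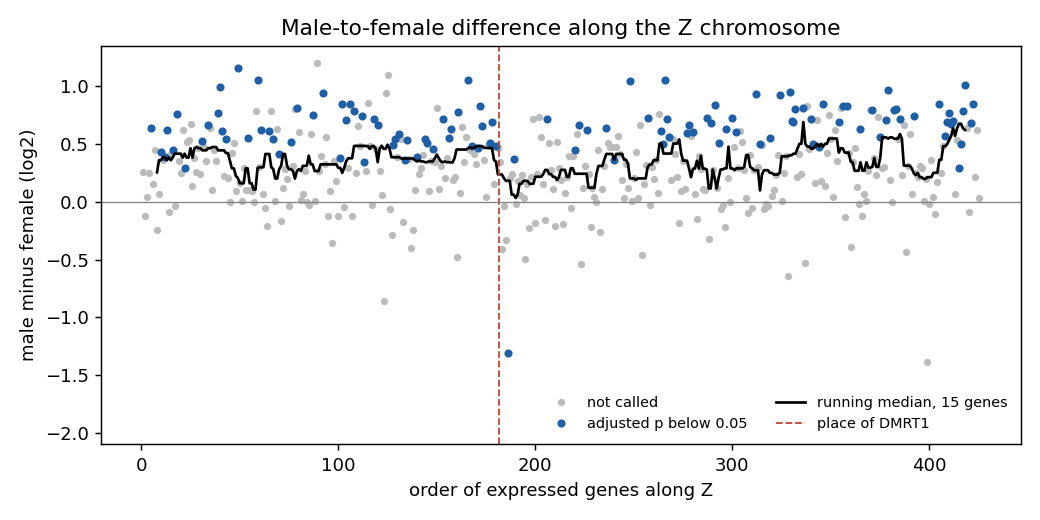
Male-minus-female difference (log2) of each of 425 expressed Z genes, in gene order along Z; blue points passed at an adjusted p below 0.05, the line is the running median of 15 genes and the dashed line marks the place of DMRT1. The running median stays above 0 along Z, with its lowest value, 0.033, beside DMRT1 and its highest, 0.69, in the later part of the chromosome.

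Z genes with a known copy on W were further apart between the sexes than other Z genes. SPIN1, a chromatin reader, was higher in males by 0.73 (SE 0.092), RASA1, a Ras regulator, by 0.72 (SE 0.13), the basic transcription factor gene BTF3 by 0.65 (SE 0.060) and the AAA ATPase gene VCP by 0.54 (SE 0.061). These 4 were named after their values were seen. Of 17 such genes, 9 passed, all higher in males, while SUB1 gave −0.052 (adjusted p = 0.870). The 15 expressed ones shifted by 0.53 (SE 0.029) against autosomes, and Z genes without a W copy by 0.38 (SE 0.019). The difference was 0.16 (SE 0.041, exact permutation p = 0.00794), and without female E it was 0.15 (exact permutation p = 0.0571). With the mean of probe sets per gene it was 0.10 (exact permutation p = 0.0317). These tests permute pools with the genes fixed, so they do not ask whether another set of 15 Z genes would shift as far. No draws of other Z genes, matched on signal or not, were made for this set.

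Few autosomal genes were called as different between the sexes. C8B, a terminal complement component, was higher in males by 0.83 (SE 0.14, adjusted p = 0.00677), the orphan nuclear receptor NR2C1 by 0.61 (SE 0.063) and B2M, the light chain of class I major histocompatibility molecules, by 0.56 (SE 0.097). C2orf88 (0.79), SH3BGRL2 (0.73), the endothelial transcription factor KLF2 (0.59), GCHFR, the feedback regulator of GTP cyclohydrolase (0.57), and GINM1 (0.47) were also called higher in males. PLA2G5, a secreted phospholipase, was higher in females by the widest margin among the named autosomal genes, −2.34 (SE 0.36, adjusted p = 0.00423). The chaperonin subunit CCT3 (−1.05, SE 0.20), the tetraspanin TSPAN8 (−0.86, SE 0.13), ZNF385D (−0.86), C1D (−0.67), HAUS3 of the augmin complex (−0.63), TIGAR (−0.61) and NOP16 (−0.55) were higher in females. In all, 16 autosomal genes passed as higher in males and 19 as higher in females. In simulated data 10 of 12172 unchanged autosomal genes passed this test, so some of the 35 may be false calls, and with adjustment over autosomal genes alone 1 gene passed. A simulated log2 difference of 0.5 was called for 23 of 64 genes, so real differences of that size may have been missed. Of the 18 autosomal genes named here and among the lists, C8B, NR2C1, B2M, PLA2G5, TSPAN8 and C1D passed in all 9 fits that each left out 1 pool. Of these 6, C8B and B2M lost their call without a mean-variance trend, with the mean of probe sets per gene and with the letter as a block, C1D without a trend and with the block, and NR2C1 with the mean of probe sets. The count of autosomal genes fell to 13 without female B, 17 without male B, and 19 without either female D or male E. It was 13 without a mean-variance trend, 17 with the mean of probe sets per gene, 48 above the 50th percentile of signal (20 higher in males, 28 in females) and 51 above the 75th (22 and 29). The balance turned toward males with centred arrays (15 and 12) and without female C (17 and 11). GCHFR gave −0.79 with the plain probe sets alone (adjusted p = 0.723), where its dimmest probe set stands for the gene.

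Over all probe sets, 239 of 38439 passed, 177 higher in males and 62 higher in females. Probe sets without an assigned gene supplied 39 of these, 23 higher in males and 16 in females.

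Genes of sterol and bile acid synthesis leaned to males. Of 22 autosomal members, 19 had estimates above 0, with a median of 0.19, among them SC5D (0.56, SE 0.15), FDPS (0.39, SE 0.15) and SQLE (0.42, SE 0.21), enzymes of the cholesterol pathway, while MVD (−0.41) and CYP51A1 (−0.26) lay below 0. The list passed camera (adjusted p = 4.8e-04 over 24 lists), with adjusted p = 0.416 with an estimated correlation. No member passed singly over all genes, and 0 passed adjusted over the list alone (limma, 3 at an unadjusted p below 0.05). Its Z members were called higher in males for AMACR (0.54, SE 0.064), a racemase of bile acid synthesis, and STARD4 (0.67, SE 0.087), a sterol carrier, while HMGCS1 on Z was at −0.36 (adjusted p = 0.835).

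Macrophage and granulocyte markers also leaned to males. The 18 members had a median of 0.22, with 12 estimates above 0, among them the complement gene C1QC (0.53, SE 0.15), the protease CTSS (0.41, SE 0.12) and LCP1 (0.28, SE 0.10), while LYZ was at −0.26 (SE 0.59). The list passed camera (adjusted p = 0.0127), with adjusted p = 0.416 with an estimated correlation. Over all genes 0 members passed, and 2 passed adjusted over the list alone, C1QC and CTSS. The camera call was lost without male B (adjusted p = 0.0640), female C (adjusted p = 0.0678) or male E (adjusted p = 0.0862).

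Gonad and adrenal markers passed camera on the male side (adjusted p = 0.0201), with adjusted p = 0.413 with an estimated correlation. The median of 13 members was 0.21, and STAR, which carries cholesterol into mitochondria for steroid synthesis, was at 1.10 (SE 0.36), DBH at 1.14 (SE 0.43) and TH at 0.89 (SE 0.40), the last pair being enzymes of catecholamine synthesis. The ovarian gene FOXL2 was at −0.47 (SE 0.54) and the testicular hormone gene AMH at −0.016 (SE 0.13). No member passed over all genes or adjusted over the list alone. Mean signals of DBH (7.73) and TH (6.998) were below the brightest unspiked control, and with only the 5 members above the level filter the median was −0.0039 (adjusted p = 0.928). The call was also lost without male B (adjusted p = 0.0577), female C (adjusted p = 0.158), female D (adjusted p = 0.0537) or male E (adjusted p = 0.0952).

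Cell proliferation genes leaned to females. Of 20 members, 16 had estimates below 0, with a median of −0.14, among them TYMS (−0.29, SE 0.077) and RRM2 (−0.21, SE 0.068), which make DNA precursors, and PCNA (−0.16, SE 0.066), a clamp for DNA polymerases. The list passed camera in the female direction (adjusted p = 0.0201), with adjusted p = 0.416 with an estimated correlation. Over all genes 0 members passed, and 1, TYMS, passed adjusted over the list alone. Erythroid markers, whose cells also divide in embryonic tissue, had a median of −0.17, with 9 of 10 members below 0, and did not pass (adjusted p = 0.128). The list index of proliferation in male E (−0.20) was the lowest of the male pools, the others lying between −0.045 and −0.015, and without male E the list did not pass (median −0.051, adjusted p = 0.164). It was also lost without female B (adjusted p = 0.0976) or female D (adjusted p = 0.0539).

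Liver function lists did not pass. Secreted hepatocyte proteins had a median of 0.014 (adjusted p = 0.213), with complement C3 called higher in males at 0.29 (SE 0.060), drug metabolism 0.022 (adjusted p = 0.128), with 0 members passing over all genes and 2 adjusted over the list alone (SULT1B1, 0.41, and CYP3A5, 0.90), and egg-yolk and oestrogen-responsive genes −0.0027 (adjusted p = 0.958). The growth hormone and IGF axis had a median of 0.11 (adjusted p = 0.115). With 1 pool left out this median ran from 0.0084 to 0.20, and the list passed in 0 of 9 fits. Its member STAT5A, a transducer of growth hormone signals that was matched through its alias STAT5B, was called higher in males at 0.31 (SE 0.065). Fatty acid synthesis and storage was at −0.015 (adjusted p = 0.893), fatty acid oxidation and ketone synthesis at 0.084 (adjusted p = 0.207), and glycolysis and gluconeogenesis at −0.0068 (adjusted p = 0.9998). Steroid hormone conversion and receptors was at 0.028 (adjusted p = 0.958), and one-carbon, amino acid and urate metabolism at 0.0021 (adjusted p = 0.963). The interferon response had a median of 0.16 (adjusted p = 0.213), with B2M called, chaperones and unfolded protein response −0.068 (adjusted p = 0.443), immediate early genes −0.056 (adjusted p = 0.963), with KLF2 called, and the circadian clock −0.095 (adjusted p = 0.958). C3, STAT5A, B2M and KLF2 also passed adjusted over the list alone. Over all genes, C3 and STAT5A each passed in only 2 of the 9 fits without 1 pool and KLF2 in 1. C3 was lost in 5 of 11 other settings, STAT5A in 4 and KLF2 in 3, and those 11 include quantile normalization, the setting used. In values as deposited, secreted hepatocyte proteins passed with a median of 0.16 (adjusted p = 1.2e-04), drug metabolism with 0.062 (adjusted p = 0.0303) and fatty acid oxidation with 0.12 (adjusted p = 0.0387).

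Markers of other tissues and cell types gave these medians, none of which passed: endothelium, stellate cells and fibroblasts 0.011 (adjusted p = 0.958), bile duct and gall bladder −0.015 (adjusted p = 0.963), exocrine and endocrine pancreas −0.42 (adjusted p = 0.377), and striated muscle and kidney −0.28 (adjusted p = 0.184). With 1 pool left out, the pancreas median ran from −0.74 to −0.093, and the list passed in 1 of 9 fits (camera adjusted p = 0.0477). Striated muscle and kidney ran from −0.48 to −0.19 and also passed in 1 (camera adjusted p = 0.0464). The pancreatic genes PNLIPRP1 (−0.83, SE 0.55), a relative of the listed PNLIP that was matched through an alias, and CELA2A (−0.63, SE 0.44) did not pass. The muscle genes MYL1 (−1.002, SE 0.47) and TNNT3 (−0.80, SE 0.44) did not pass either.

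The mitochondrial respiratory chain had a median of 0.037, with 28 of 35 autosomal members above 0, and did not pass (adjusted p = 0.0666). It passed in values as deposited (median 0.13, adjusted p = 1.0e-06) and above the level filter (adjusted p = 0.0463). Ribosomal proteins had a median of −0.0067 (adjusted p = 0.963), and in values as deposited the median was 0.11 (adjusted p = 4.0e-08), so the direction of this family depends on the scaling. No list of the 24 passed camera with an estimated correlation, fry after adjustment, or the adjusted permutation of pools. The permutation of pools gives no p below 0.00794, so 1 list alone could not pass it after adjustment over 24 lists. Failure after adjustment therefore says little against any list. Unadjusted, the exact permutation p was 0.0238 for sterol and bile acid synthesis and 0.0714 for macrophages and granulocytes. It was 0.0159 for gonad and adrenal and 0.111 for proliferation. The macrophage and proliferation lists thus did not reach 0.05 even before adjustment. Estimated correlations of these lists were 0.11, 0.16, −0.019 and 0.17 in that order, against the preset 0.01. With plain probe sets alone 1 list passed, sterol and bile acid synthesis, and with the mean of probe sets per gene the proliferation list did not pass. The median and the camera direction differed in sign for 7 lists, and the mean and the median for 4.

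Called Z members of these lists were higher in males. Of 27, 8 were called higher in males and 0 higher in females (limma): beside AMACR and STARD4 these were the fatty acid thiolase ACAA2 (0.43, SE 0.064), the peroxisomal enzyme HSD17B4 (0.74, SE 0.079), the clock-linked repressor NFIL3 (0.50, SE 0.10), the respiratory chain subunits NDUFS4 (0.78, SE 0.090) and COX7C (0.50, SE 0.046), and the ribosomal protein RPL17 (0.39, SE 0.053). NFIL3 passed in only 3 of the 9 fits without 1 pool (highest adjusted p = 0.102) and was lost with centred arrays, without a trend and with the letter as a block. ACAA2 was lost without a trend and with the block, NDUFS4 with the mean of probe sets per gene, COX7C with plain probe sets and RPL17 without a trend.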

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

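Tests chosen after the result was seen were the pseudocount test of dim against bright genes and the further counts of autosomal genes in other splits, while the run beside DMRT1 was noticed in the data before its tests were written.

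A pool far from the others of its sex was found in 15 of 324 groups of values (4.63%), and chance gives about 1 in 20. The spiked controls of male B averaged log2 14.69, the other males 14.10 to 14.17. The egg-yolk list index of female E was 0.43, the other females −0.18 to −0.020. The erythroid list index of female A was 0.29, the other females −0.014 to 0.057. The proliferation list index of male E was −0.20, the other males −0.045 to −0.015. Among single genes, HNRNPKL was 6.30 in male E, APTX 10.83 in female C, B2M 13.47 in female B, PLA2G5 8.30 in male A, C1D 13.15 in female B and THRSP 6.06 in female E. Further values were C1QC 11.68 in male A, CEL 6.31 in female E, CRY1 13.76 in male D, NPAS2 6.90 in male A and COX7C 16.85 in female D.

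The run from VLDLR to GLDC, with a median of 0.033 and 1 expressed gene between it and DMRT1, may be a region of lower male-to-female ratios, but 0.265 of shuffled gene orders held a run as low, so chance order stays open. Of draws of other Z genes of like signal, with the run counted as a draw, 0.0016 had a median as low, and 0.0019 did when SLC1A1 was left out of the run. Those draws were written as able to exclude low signal and a single deviant gene. They ignore that the run was picked as the lowest of all runs, so the shares overstate how unusual it is, and low signal stays open. With 7 of its 15 estimates below 0, the low median does not rest on SLC1A1 alone. A median of 15 genes moves little with any 1 gene, so this is not a test of a single deviant gene. Of the windows around DMRT1 fixed before the run was seen, 2 Mb gave −0.099 (exact permutation p = 0.0159), 5 Mb −0.029 (p = 0.190) and 10 Mb −0.027 (p = 0.183). A difference between the sexes in the region beside DMRT1 stays open and was not tested in other tissue.

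Dim Z genes shifted less than bright ones, by 0.31. With a pseudocount at the 1st percentile the difference was 0.28, which argues against the pseudocount as the whole cause. Among 486 Z genes above all unspiked controls, the brighter part shifted by 0.41 and the dimmer by 0.30 (difference 0.11, exact permutation p = 0.00794). The pattern is thus not confined to genes at the level of the controls. This split was written as able to exclude background as the whole cause. It cannot, since background added to signal also lowers the ratios of genes above the controls. Background for part or all of the pattern stays open, and 60.6% of the dimmest group lie at or below the brightest unspiked control. A biological link between level and dose response is a hypothesis that may remain, and it was not tested.

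Ratios of Z genes spread more widely (SD 0.35) than those of autosomal genes of like signal (median SD of draws 0.23, highest 0.32). Of 10000 draws, 0 were as wide (a share of 1e-04 only because the real set is counted as a draw), which argues against noise around a single ratio; without SLC1A1 the SD was 0.35. Of the 255 Z genes over the 75th percentile of signal, the brightest 64 shifted by 0.073 less than the rest (difference −0.073, exact permutation p = 0.0159). The rest of these 255 had an SD of 0.37, against at most 0.34 in draws of autosomal genes of like signal. Of those draws 0 were as wide (1e-04 by the same count), which argues against saturation as the whole cause. This SD covers fewer genes than the SD of 0.35 above and is not to be set against it. Gene-by-gene differences in dose response may be the source, as a hypothesis found and tested on the same data. Non-specific binding of probes was not tested.

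Other splits of the 9 pools into 4 and 5 were drawn (100, the real one included). As many probe sets (239) came from 1 split, the real one, with at most 3 from any other. As many Z genes higher in males (115) came from 1, with at most 0 from any other, and as many W genes (10) from 1, with at most 0. These counts argue against chance, though 100 splits allow no share below 1 in 100. As many autosomal genes (35) came from 1, with at most 2 from any other, but the Z and W calls that loosen the adjusted limit are missing from the other splits. At the p limit of the real split (6.0e-04) 35 still came from 1, with at most 20 and a median of 7 from the others, which argues against chance as the source of the whole number. Adjusted over autosomal genes alone, 1 gene passed, and 7 of the 100 splits gave as many, so chance stays open for single autosomal calls. As many called lists (4) came from 3 of the 100 splits, with 5 as the highest of the others, so the number of lists alone is weak evidence for any of them, and 0 lists passed with an estimated correlation.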

How the results depend on the processing

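Values as deposited, plain probe sets, camera with a trend, the synonym match of W copies and PODXL in its list were chosen after the result was seen.

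The Z shift kept its direction and an exact permutation p at or below 0.0286 in every setting run except the block by letter, from 0.34 without a level filter to 0.42 above the 75th percentile, and 0.36 to 0.39 when 1 pool was left out. Quantile normalization is the setting used and so repeats it, and eBayes without a trend leaves camera as it is. The median of all genes moved by less than 0.02 from that of the setting used. Signal over background limits what dim genes can show. Except where fewer genes, probe sets or pools were tested, the cause was not tested for any change below.

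As a block, the letter gave 158 probe sets, 13 autosomal genes, 75 Z genes higher in males and 2 lists, and the Z shift (0.39), the difference by level (0.32) and the W-copy difference (0.16) each had an exact permutation p = 0.125, the smallest that 4 pairs allow. A check of pairing gave own-letter correlations of 0.114, −0.074, −0.0359 and 0.176, the highest of a male pool's correlations for A and E only, so the letters do not show pairing. Without a trend, eBayes gave 76 probe sets, 13 autosomal genes and 72 Z genes higher in males. The mean of probe sets per gene gave 17 autosomal and 76 Z genes. It also gave 0.10 for the W-copy difference (exact permutation p = 0.0317). Autosomal genes numbered 48 above the 50th percentile and 51 above the 75th, and Z genes higher in males 132 and 128. W genes numbered 6 above the 50th percentile and 2 above the 75th, since the filter removes dim W genes. Plain probe sets gave 146 probe sets, 1 list and −0.065 near DMRT1, and the 2 Mb window −0.099 (10 Mb, −0.027). Lists numbered 9 (8 toward males) with centred arrays and 9 as deposited, 5 with camera's trend, where the respiratory chain joined (adjusted p = 0.0115), and 4 with PODXL kept; W copies by synonym gave 0.13.

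With 1 pool left out, autosomal genes numbered 13 to 35, lists 1 to 6, probe sets 171 to 220 and Z genes higher in males 91 to 104. The difference near DMRT1 ran from −0.045 to 0.00080 (without male B), and the W-copy difference from 0.14 to 0.19, with an exact permutation p = 0.0571 without female E (0.15). Lists numbered 1 without male E and 2 without male B, female C or female D.

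Apart from GCHFR, the gonad and adrenal list and ribosomal proteins, values that turned in sign had passed in neither setting. Centred arrays gave APOB 0.038, GPI 0.018, HBAD 0.097 and RPL27A 0.088, and the lists of egg-yolk genes 0.038, glycolysis 0.082, bile duct 0.059 and ribosomal proteins 0.12 (adjusted p = 1.7e-07). As deposited these were APOB 0.022, GPI 0.0016, HBAD 0.081, RPL27A 0.072, egg-yolk genes 0.022, glycolysis 0.066, bile duct 0.043 and ribosomal proteins 0.11. The mean of probe sets gave MCM6 0.28, CRY1 0.063, TEF −0.0050, RPL29 −0.020, egg-yolk genes 0.066, fatty acid synthesis 0.029 and one-carbon metabolism −0.042. Plain probe sets gave GCHFR −0.79, GPI 0.10, MCM6 0.032, RPL29 −0.082, glycolysis 0.032, one-carbon metabolism −0.011 and pancreas 0.065. The 50th percentile filter gave fatty acid synthesis 0.0069 and gonad and adrenal −0.0039; the 75th gave these same values, one-carbon metabolism −0.021, endothelium −0.0023 and pancreas 0.011. The pseudocount at the 25th percentile gave egg-yolk genes 0.0016.

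Leaving out 1 pool, list medians crossed 0 for egg-yolk genes (−0.11 to 0.20), fatty acid synthesis (−0.040 to 0.062), glycolysis (−0.014 to 0.014), steroid conversion (−0.043 to 0.076), one-carbon metabolism (−0.040 to 0.050), endothelium (−0.050 to 0.062), bile duct (−0.15 to 0.012), interferon response (−0.016 to 0.20), immediate early genes (−0.19 to 0.016), clock (−0.10 to 0.00076) and ribosomal proteins (−0.022 to 0.0018). Of values of named genes that had passed, over alternatives keeping all pools, 446 kept direction and call, 51 lost the call and 1 turned. These alternatives include quantile normalization, which repeats the setting used and so adds to the 446 by construction. With 1 pool left out, 345 kept both and 78 lost the call.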

Other observations

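Except for the W-copy comparison, tests in this part were chosen after the result was seen.

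Among mitochondrial ribosomal proteins, the 5 encoded on Z were all called higher in males: MRPL17 (1.05), MRPS30 (0.85), MRPL50 (0.83), MRPS27 (0.69) and MRPS36 (0.54), with a median of 0.83. Of 62 encoded on autosomes, 1 was called, MRPL53, at −0.36 (adjusted p = 0.0142), and the median was −0.028. The set was taken up because MRPL17 stood among the top Z genes, so it is left out here: the other 4 Z members had a median of 0.76 and other expressed Z genes 0.35, and of 10000 draws of 4 other Z genes of like signal 87 (0.87%) had a median as high. That these 4 were called was known before the draws were made. A difference between Z and autosomal members is the Z shift itself and says nothing of this family.

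Other Z genes of the liver gave values without a call: the growth hormone receptor GHR 0.56 (SE 0.13, adjusted p = 0.0587), the terminal complement component C7 1.20 (SE 0.29, adjusted p = 0.0762), the assembly factor NDUFAF2 1.10 (SE 0.25, adjusted p = 0.0587) and the taurine pathway enzyme CDO1 −1.39 (adjusted p = 0.0918). These 4 were named after their values were seen.

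Probe sets of Z genes with a W copy could also bind the W transcript, which would raise female signal and lower the male-to-female difference of these genes. The comparison with other Z genes was planned for this reason, while its prediction was written after the value was seen. The 15 expressed genes shifted more than other Z genes, by 0.16 (SE 0.041, exact permutation p = 0.00794). That is the opposite direction. A larger shift is what defined the pattern, and W binding could only lower it, so the outcome was fixed in advance. The comparison therefore cannot test W binding. Whether such binding lowers the shift of these genes by some amount was not tested and stays open.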
